A study of Mus musculus with 10 samples.

How the data were processed

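Ribosome-depleted total RNA from 100 ng per library was sequenced as 50 bp single-end reads on a NextSeq 500, per the labels, in 10 libraries of mouse splenic B cells that form 5 groups of 2. RNA came from fewer cells in Phase II than in Phase I, so phase, culture time, cell input and any difference of batch cannot be told apart. The values are TPM, the unit in the deposited table, by transcript of the build mm10. The submitters' processing notes name HISAT2, Salmon, featureCounts, HTSeq and DESeq2, and their roles, order, versions and use of strand are not given in the sources used here. How resting cells were purified, and whether Phase II replicates are pools of mice, is not stated there.

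The table holds 13128 transcripts with values, and each library sums to 1000000 TPM over them. Of these, 63 without a usable symbol were left out and 13065 were summed by symbol into 6610 genes, 3744 with 1 transcript and 2866 with more, of which 734 were at 0 in every library. TPM is relative to the transcripts listed and keeps no count, so the depth is unknown, no counting interval is given, and no count model was fitted. Coordinates are those of GRCm38.p6.

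Group comparisons used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 1 linear model per gene over all 10 libraries, group as the only term, empirical Bayes moderation with a mean-variance trend and Benjamini-Hochberg adjustment (two-sided, threshold 0.05). Genes with at least 1 TPM in at least 2 libraries were tested, 4427 in all. The design leaves 5 residual degrees of freedom, so every comparison borrows its spread from all groups. The comparisons were div0 and div12 against naive, div12 against div0, div12_48_d against div12_48_u, each Phase II group against div12, and the difference of the Phase II and Phase I division contrasts. Replicates of the naive group differed most, with an SD of 0.553 of the log2 ratio over genes and 340 genes more than 2-fold apart, against 39 in div0, 33 in div12, 65 in div12_48_u and 55 in div12_48_d.

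Of 39 gene lists, 35 with at least 3 tested members were tested with camera, which compares a list with the other genes, at a preset correlation of 0.01 and with adjustment over the lists of a comparison. They cover cell cycle, metabolism, signalling, apoptosis, B cell states and other cell types. Most lists are partial, with 18 of 38 planned G2/M, 23 of 38 G1/S and 8 of 15 plasma cell genes tested. Camera was repeated with an estimated correlation. Fry, which tests a list by itself, was run. Overlap of the division contrasts was tested with one-sided Fisher's exact tests over genes.

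Named genes follow a rule: per comparison, the 6 called genes with the largest rise and the 6 with the largest fall, among genes with a mean of at least 10 TPM in the higher group and no overlap between libraries of the groups, without unnamed gene models, immunoglobulin segments, small RNAs and histones (5 each way for the difference, where 0 were called). The rule adds 2 to 4 called members of each list described, or up to 2 of the most abundant members where none was called, and Birc5, Aurkb, Mki67, Myc, Ccnd2, Ccnd3, Cdkn1b and Prdm1 in every comparison. A few genes that the rule takes are not reported here. Cd9 and Jchain for the difference, Hbb-b1 for the overlap, Tnfrsf17, and the genes of the last part were singled out after their values were seen where the rule did not take them. The groups, comparisons, tests, lists, rule and most alternatives were chosen before the data were examined.

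Alternatives changed 1 choice at a time: a pseudocount of 0.1 or 5, no filter or a filter at 5 TPM, median-ratio scaling, quantile normalization, a fit of the compared groups alone, the replicate number as a block, no trend, a fold of at least 2, the correlation and fry for lists, and leaving out each library in turn. A fit without the naive group, the most abundant transcript of each gene, and leaving out markers of other cells with immediate early genes were added after seeing the data. When a library was left out, the lone library of its group was assumed to vary like the other groups.

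The model was tested on simulated data of the same size with 200 changed genes in 5 runs. Of genes changed 2-fold, 90.7% to 93.1% were called in group comparisons and 72.4% in the difference. Of genes changed 4-fold, at least 97.8% were called, and 4.60% to 5.86% of calls were false. Rates for low genes or naive libraries may differ. Figures and tables used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.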

Results

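The series measured RNA of splenic B lymphocytes from C57BL/6 mice, an inbred laboratory strain, through a first and a second round of division in culture. Its title names survivin in the G1 phase that follows mitosis. There were 5 groups of 2 libraries. Resting cells form the group naive. Phase I cells received a pulse of antibodies against IgM, the antigen receptor, and CD40, a co-stimulatory receptor, and were taken at 48 h, either undivided (div0) or divided (div12). For Phase II, div12 cells spent a further 48 h in 0.12 µg/ml anti-CD40 and were sorted into cells that had not divided again (div12_48_u) and cells that had (div12_48_d). The labels call the Phase I replicates independent and made of pools of 4 to 5 mice each. The values are TPM, transcript abundances scaled to the same total in each library, for 6610 gene symbols, of which 4427 passed the filter on low values. Sequencing depth is unknown. TPM levels below are the mean ± SD with n = 2 libraries, and log2 fold changes are on the log2(TPM + 1) scale with their standard error, which understates the change of low genes. A gene is said to rise or fall where limma gave a Benjamini-Hochberg adjusted p under 0.05, two-sided, over the 4427 genes. The listed symbols cover 6320 of 21896 protein-coding genes of the reference (28.9%), genes outside them were not analysed here, and members of near-identical families (Hba-a1, Gbp2b, Bcl2a1a, Ifi205, Klra8, Cd1d2) may hold reads of relatives.

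Birc5 encodes survivin, the inhibitor of apoptosis family member that also belongs to the chromosomal passenger complex of mitosis. The gene lies on chromosome 11 from 117849237 to 117855743 (GRCm38.p6) and is listed with 2 transcripts, summed here. Its level was 30.7 ± 3.90 TPM in naive cells, 329.7 ± 60.3 in div0, 522 ± 24.8 in div12, 106 ± 10.4 in div12_48_u and 294 ± 31.3 in div12_48_d. Cells that had divided held more Birc5 RNA than their undivided counterparts in both phases, by 0.67 ± 0.15 in Phase I (adjusted p = 0.0361) and by 1.47 ± 0.15 in Phase II (adjusted p = 7.53e-04). The Phase I call of Birc5 was marginal: its adjusted p was 0.254 without div0 replicate 1, 0.0735 without div0 replicate 2, 0.0909 and 0.145 without div12 replicate 1 or 2, 0.0504 without either div12_48_u library, and between 0.0528 and 0.0644 with a replicate block, no trend, no filter, the compared groups alone or the most abundant transcript (the last added after seeing the data). Aurkb, the kinase of the passenger complex, had the same order of group means, from 31.1 ± 6.37 TPM in naive cells to 204 ± 53.7 in div12. The proliferation marker Mki67 ran from 59.8 ± 6.14 TPM in naive cells to 619 ± 122 in div12.

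**Figure D1:**
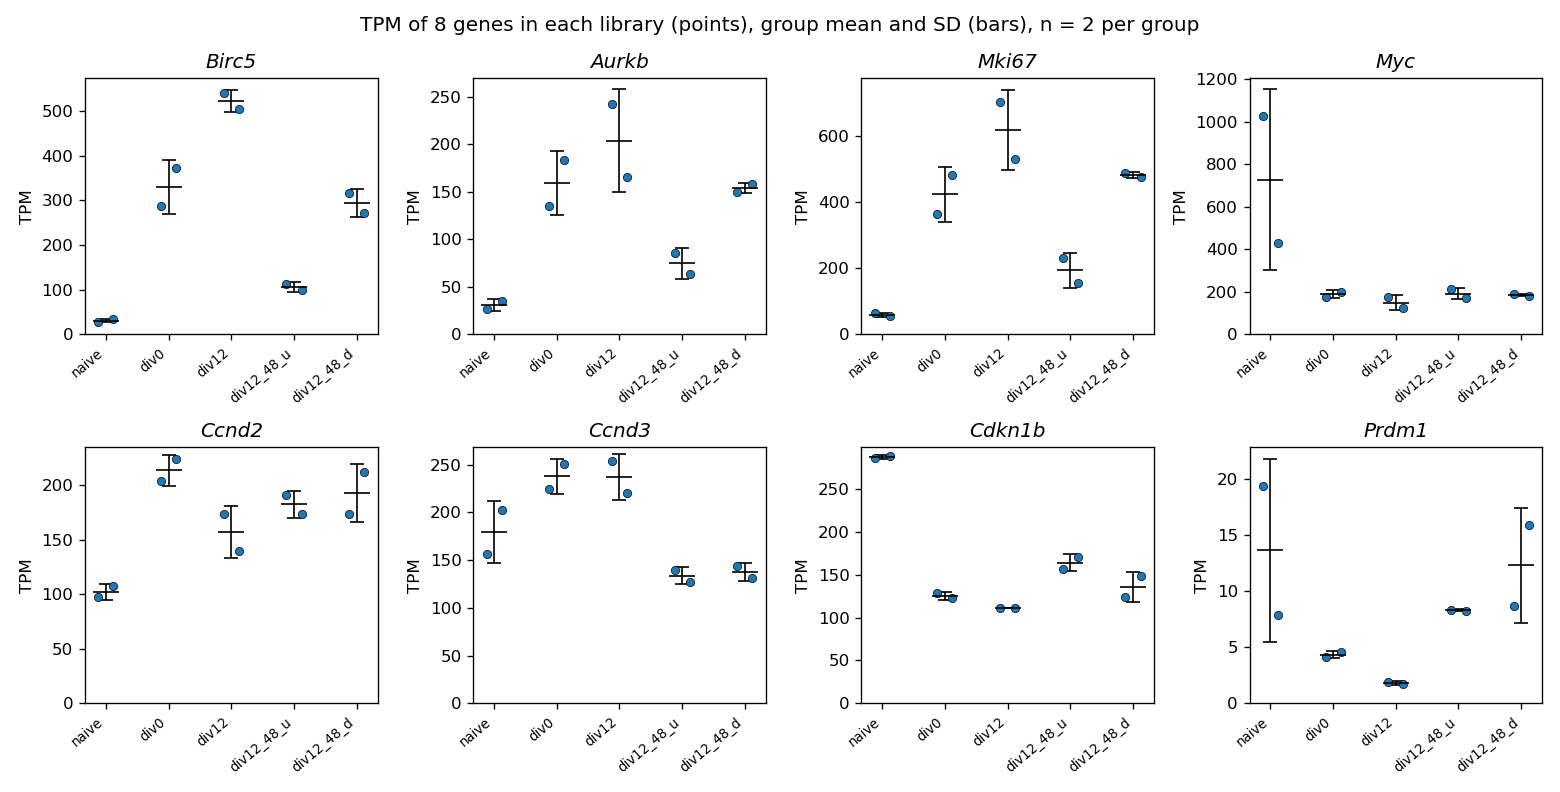
TPM (y axes, linear from 0) of 8 genes chosen before the data were examined, in the 5 groups along the x axes. Points are single libraries, horizontal bars group means and whiskers SD (n = 2), and the group means of Birc5 are 330 TPM in div0 and 522 TPM in div12.

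The first comparison set activated but undivided cells against resting cells (div0 against naive). Lists of cell-cycle genes were called higher in activated cells, and those of quiescence and resting B cell genes lower. Birc5 rose by 3.38 ± 0.15 on the log2 scale, a 10.4-fold change, Mki67 by 2.80 ± 0.21 and Aurkb by 2.32 ± 0.24. In the list of G2/M and mitosis genes 18 of 18 members rose (18 adjusted over the list alone), among them Bub1 (3.06 ± 0.21), a spindle checkpoint kinase, Tpx2 (2.90 ± 0.18) and Ccnb2 (2.84 ± 0.17), a B-type cyclin. Camera gave G2/M genes adjusted p = 6.81e-18, and adjusted p = 0.266 with an estimated correlation. In the list of G1/S and replication genes 21 of 23 members rose and 1 fell (21 and 2 adjusted over the list alone), led by Rrm2 (2.97 ± 0.17), a subunit of ribonucleotide reductase, Uhrf1 (2.86 ± 0.19) and Gins2 (2.05 ± 0.12). Camera gave G1/S genes adjusted p = 2.77e-15, and adjusted p = 0.266 with an estimated correlation. All 3 tested passenger complex genes rose (3 adjusted over the list alone), Incenp (1.83 ± 0.23) being the other one. Camera gave the passenger list adjusted p = 3.83e-04, and adjusted p = 0.266 with an estimated correlation. In the DNA repair list 12 of 15 members rose (13 adjusted over the list alone), including Chek1 (2.30 ± 0.21), a checkpoint kinase. Camera gave DNA repair genes adjusted p = 6.41e-09, and adjusted p = 0.266 with an estimated correlation.

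The chemokine Ccl22 went from 2.22 ± 0.539 to 149 ± 40.2 TPM (5.53 ± 0.44), Wnt10a from 6.01 ± 1.64 to 161 ± 3.65 (4.55 ± 0.23), and Wnt10b rose by 3.82 ± 0.30. The guanylate-binding protein gene Gbp2b rose by 4.38 ± 0.24, Hspg2, which encodes the proteoglycan perlecan, by 3.90 ± 0.34, and Adipoq by 3.55 ± 0.23. In the list of NF-kB and CD40 response genes 11 of 25 members rose and 6 fell (11 and 6 adjusted over the list alone), with Fas (2.75 ± 0.21), a death receptor, and Traf1 (1.99 ± 0.13) among the rises. Camera gave NF-kB and CD40 response genes adjusted p = 0.00350, and adjusted p = 0.292 with an estimated correlation, a call lost with quantile normalization (adjusted p = 0.0588). In the BCL2 family of apoptosis genes 5 of 13 members rose and 2 fell (7 and 2 adjusted over the list alone). Pro-apoptotic Bid (2.11 ± 0.19) and Bbc3 rose and Bmf fell (-1.43 ± 0.15). Anti-apoptotic Bcl2a1a (2.06 ± 0.19) and Bcl2l1 (1.70 ± 0.20) rose and Bcl2 fell. Camera gave the BCL2 family adjusted p = 0.00440, and adjusted p = 0.266 with an estimated correlation.

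Several metabolic lists were called higher in the same comparison. In oxidative phosphorylation 16 of 24 members rose (16 adjusted over the list alone). Camera gave oxidative phosphorylation adjusted p = 1.20e-07, and adjusted p = 0.277 with an estimated correlation. All 16 tested ribosomal protein genes rose (16 adjusted over the list alone). Camera gave ribosomal protein genes adjusted p = 2.50e-09, and adjusted p = 0.277 with an estimated correlation. In cholesterol synthesis 8 of 13 members rose (8 adjusted over the list alone), including Sqle (1.57 ± 0.24) and Idi1 (1.35 ± 0.21). Camera gave cholesterol synthesis adjusted p = 1.35e-05, and adjusted p = 0.292 with an estimated correlation. Of 4 serine and one-carbon genes 3 rose (3 adjusted over the list alone), Psat1 by 1.46 ± 0.18 and Phgdh by 1.15 ± 0.12. Camera gave one-carbon genes adjusted p = 0.00522, and adjusted p = 0.277 with an estimated correlation. In glycolysis 7 of 16 members rose and 4 fell (7 and 4 adjusted over the list alone), the enzyme gene Gapdh among the rises (1.07 ± 0.11). The glycolysis list had camera adjusted p = 0.0202, and adjusted p = 0.371 with an estimated correlation, a call lost without naive replicate 2 (adjusted p = 0.0719). Among D-type cyclins and their partners 6 of 10 members rose and 2 fell (6 and 3 adjusted over the list alone), Ccnd2 rising by 1.06 ± 0.14, Ccnd3 by 0.41 ± 0.14 and Cdk4 by 0.93 ± 0.08. Camera gave the D cyclin list adjusted p = 0.0203, and adjusted p = 0.371 with an estimated correlation, a call lost with quantile normalization (adjusted p = 0.0665). The call of Ccnd3 was lost without naive replicate 1 (adjusted p = 0.172), without div0 replicate 1 or 2 (adjusted p = 0.0611 and 0.173) and in a fit of these groups alone (adjusted p = 0.0946).

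Genes associated with quiescence went the other way. In that list 1 of 18 members rose and 15 fell (2 and 15 adjusted over the list alone). Camera gave quiescence genes adjusted p = 0.00522, and adjusted p = 0.292 with an estimated correlation. Klf4 (-5.55 ± 0.26) and Klf2 (-4.37 ± 0.24), transcription factors of resting lymphocytes, and Tsc22d3 (-5.22 ± 0.26) fell most, and the CDK inhibitor Cdkn1b fell from 287 ± 2.17 to 125 ± 4.49 TPM (-1.19 ± 0.10). Receptors of homing and migration fell, with Cxcr4 (-5.02 ± 0.17), S1pr1 (-3.91 ± 0.29) and Ccr7 (-2.42 ± 0.43) in a list where 2 of 18 members rose and 13 fell (2 and 13 adjusted over the list alone). Camera gave migration receptors adjusted p = 0.0177, and adjusted p = 0.266 with an estimated correlation. In the resting B cell list 1 of 20 members rose and 13 fell (3 and 14 adjusted over the list alone). Camera gave resting B cell genes adjusted p = 0.0178, and adjusted p = 0.371 with an estimated correlation. The calls of these last lists were lost without naive replicate 1 (adjusted p = 0.0565 for migration receptors and 0.0859 for resting B cell genes). Prdm1, the regulator of plasma cell fate, fell from 13.6 ± 8.18 TPM (-1.33 ± 0.38), a call lost with quantile normalization (adjusted p = 0.241), in a fit of these groups alone (adjusted p = 0.0770), without naive replicate 1 (adjusted p = 0.0848) and without div0 replicate 1 or 2 (adjusted p = 0.0806 and 0.0634).

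The naive libraries also stood apart in genes that B cells are not known for. Hba-a1, an alpha globin of red cells, fell from 2116 ± 217 TPM (-10.81 ± 0.60), the complement genes C1qa (from 158 ± 129.7 TPM to a level listed at 0) and C1qb (-6.74 ± 0.52) fell, and so did Slc40a1 (-6.53 ± 0.61), the iron exporter of macrophages. In the myeloid list 13 of 14 members fell (13 adjusted over the list alone), including Csf1r (-5.85 ± 0.61). Camera gave myeloid markers adjusted p = 3.16e-04, and adjusted p = 0.371 with an estimated correlation. In the NK list all 6 members fell (6 adjusted over the list alone), Klra8 among them (-5.01 ± 0.32). Camera gave NK markers adjusted p = 2.51e-04, and adjusted p = 0.266 with an estimated correlation. In the T cell list 7 of 9 members fell (8 adjusted over the list alone), Cd3e among them (-3.21 ± 0.18). Camera gave T cell markers adjusted p = 0.00776, and adjusted p = 0.266 with an estimated correlation, a call lost with a filter at 5 TPM (adjusted p = 0.0575). All 5 erythroid and all 3 platelet genes fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.0486 and 0.0228, and adjusted p = 0.399 and 0.277 with an estimated correlation). The erythroid call was lost with quantile normalization (adjusted p = 0.0514), with a pseudocount of 5 (adjusted p = 0.0518) and without any one div12_48_u or div12_48_d library (adjusted p from 0.0585 to 0.0603), and with a fit of these groups alone both were lost (adjusted p = 0.0896 erythroid, 0.0654 platelet). Among immediate early genes, which respond rapidly to many signals, 14 of 16 members fell (14 adjusted over the list alone). Camera gave immediate early genes adjusted p = 1.10e-04, and adjusted p = 0.292 with an estimated correlation. Fos fell from 1336 ± 517 TPM (-8.46 ± 0.72), Fosb from 499.7 ± 51.7 (-8.23 ± 0.43), and Nr4a1 (-5.25 ± 0.78) and Dusp1 (-4.94 ± 0.21) likewise. Myc fell from 728 ± 424 TPM (-1.81 ± 0.35), a mean of libraries at 1028 and 429 TPM. The summed TPM of the immediate early list was 12104 in naive replicate 1 and 6906 in replicate 2, and that of the myeloid list 777 and 2228.

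In all, limma called 2431 genes (1993 in a fit of these groups alone), 680 higher and 1751 lower in div0. The median log2 change over all genes was -0.24, and changes are best read relative to that median. With median-ratio scaling 1130 were higher and 1165 lower, with quantile normalization 1272 and 1020, and without div0 replicate 2 the count was 1573.

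Divided Phase I cells were next set against resting cells (div12 against naive). More genes were called than for div0, 858 higher and 2104 lower of 2962, and a median over all genes of -0.35. With median-ratio scaling these were 1388 higher and 1457 lower, and with quantile normalization 1472 and 1294. A fit of these groups alone called 2372 genes. Ccl22 reached 385 ± 15.4 TPM (6.92 ± 0.44), followed by Gbp2b (5.36 ± 0.24), Wnt10a (4.90 ± 0.23), Ache (4.33 ± 0.41), which encodes acetylcholinesterase, Birc5 (4.05 ± 0.15, a 16.6-fold change) and Wnt10b (3.90 ± 0.30). All 18 tested G2/M genes rose (18 adjusted over the list alone), Bub1 by 3.65 ± 0.21 and Cdk1, the mitotic kinase, by 3.39 ± 0.16. Camera gave G2/M genes adjusted p = 1.40e-15, and adjusted p = 0.278 with an estimated correlation. In the G1/S list 21 of 23 members rose and 1 fell (21 and 1 adjusted over the list alone), Rrm2 by 3.59 ± 0.17. Camera gave G1/S genes adjusted p = 6.14e-15, and adjusted p = 0.278 with an estimated correlation. Mki67 rose by 3.34 ± 0.21, Aurkb by 2.66 ± 0.24, Ccnd2 by 0.61 ± 0.14 and Ccnd3 by 0.41 ± 0.14, the last not without naive replicate 1 (adjusted p = 0.162) or div12 replicate 1 (adjusted p = 0.150), nor with these groups alone (adjusted p = 0.0951). In the oxidative phosphorylation list 21 of 24 members rose (21 adjusted over the list alone). Camera gave oxidative phosphorylation adjusted p = 2.08e-11, and adjusted p = 0.278 with an estimated correlation. In glycolysis 6 of 16 members rose and 3 fell (6 and 3 adjusted over the list alone), with Gapdh (1.76 ± 0.11) and Pgk1 (1.56 ± 0.08) among the rises. The glycolysis list had camera adjusted p = 0.00689, and adjusted p = 0.340 with an estimated correlation. Sdf2l1, an endoplasmic reticulum chaperone gene, rose by 1.36 ± 0.12, in an unfolded protein response list that was not called as a list (camera adjusted p = 0.0927, direction up, with a median of -0.13 and a mean of 0.06), except without naive replicate 1 (adjusted p = 0.0411). The list of NF-kB and CD40 response genes (10 of 25 rose and 10 fell, 10 and 10 adjusted over the list alone, camera adjusted p = 0.0697) and that of migration receptors (3 of 18 rose and 13 fell, 3 and 13 adjusted over the list alone, camera adjusted p = 0.0697), both called for div0, were not called here. Without naive replicate 1 the former was called (adjusted p = 0.0411), and 4 settings called the latter (adjusted p from 0.0106 to 0.0442).

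In the resting B cell list 17 of 20 members fell (17 adjusted over the list alone). Camera gave resting B cell genes adjusted p = 9.10e-04, and adjusted p = 0.278 with an estimated correlation. All 6 MHC class II presentation genes fell (6 adjusted over the list alone), Cd74, the invariant chain, from 45096 ± 3689.8 to 23289.8 ± 3448 TPM (-0.96 ± 0.13). Camera gave MHC class II genes adjusted p = 0.0446, and adjusted p = 0.400 with an estimated correlation, a call lost without naive replicate 1 (adjusted p = 0.114), without div12 replicate 1 (adjusted p = 0.0594), without any one Phase II library (adjusted p = 0.0510) and with median-ratio scaling (adjusted p = 0.111). It was lost too with a filter at 5 TPM, the compared groups alone or no trend (adjusted p = 0.0518, 0.0531 and 0.0644). Cdkn1b fell (-1.36 ± 0.10), and 15 of 18 quiescence genes fell (15 adjusted over the list alone) while 2 rose. Camera gave quiescence genes adjusted p = 0.0126, and adjusted p = 0.341 with an estimated correlation. Genes of plasma cells were among the falls, Jchain (-4.02 ± 0.43), Sdc1 (-2.87 ± 0.50) and Prdm1 (-2.25 ± 0.38), and their list was not called (camera adjusted p = 0.132).

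Immediate early genes stood lower in div12 than in naive cells too, as 16 of 16 members fell (16 adjusted over the list alone), with Fos (-8.77 ± 0.72) and Fosb (-8.26 ± 0.43). Their list had camera adjusted p = 2.44e-04, and adjusted p = 0.297 with an estimated correlation. Among myeloid markers 12 of 14 members fell (12 adjusted over the list alone), with C1qa (listed at 0 in div12) and C1qb (-6.64 ± 0.52), and that list had camera adjusted p = 0.00365, and adjusted p = 0.454 with an estimated correlation. Among NK markers 6 of 6 members fell (6 adjusted over the list alone), with camera adjusted p = 0.00188, and adjusted p = 0.278 with an estimated correlation. Among T cell markers 7 of 9 members fell (7 adjusted over the list alone), with camera adjusted p = 0.0424, and adjusted p = 0.278 with an estimated correlation. The T cell call was lost with a pseudocount of 0.1 (adjusted p = 0.0615), a filter at 5 TPM (adjusted p = 0.179) or the most abundant transcript (adjusted p = 0.0647), and without div12 replicate 1 (adjusted p = 0.0863). Erythroid, platelet and dendritic lists were not called (camera adjusted p = 0.0886, 0.0605 and 0.226), although Hba-a1 fell (-10.04 ± 0.60). Some settings did call the erythroid list (adjusted p from 0.00908 to 0.0354) and the platelet list (adjusted p from 0.0292 to 0.0495). Other falls were Plk2 (-6.67 ± 0.80), a p53 target, the chemokine Ccl5 (-5.88 ± 0.37) and Myc (-2.16 ± 0.35). Without the marker genes of other cell types and the immediate early genes, a choice made after seeing the data, 2378 genes were called for div0 and 2905 for div12.

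**Figure D2:**
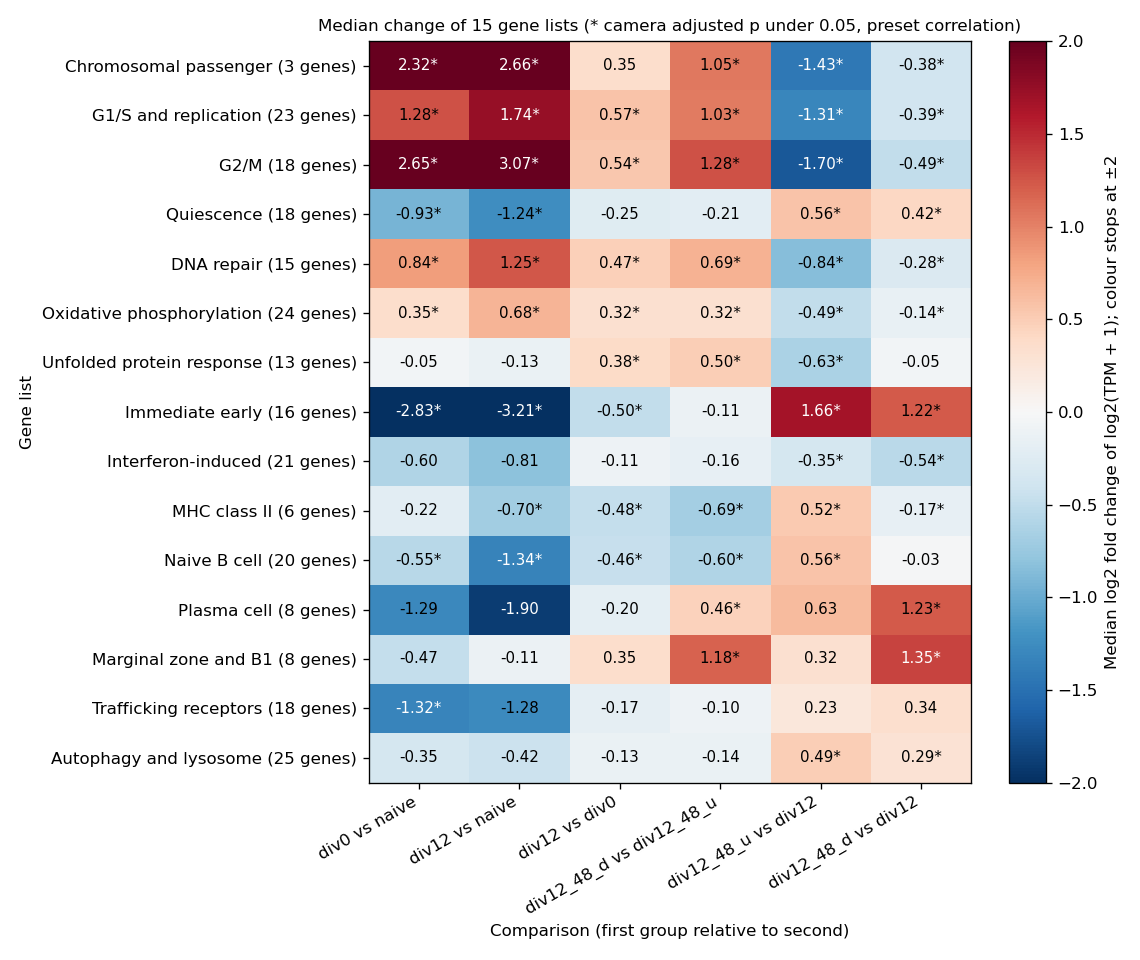
Median log2 fold change of log2(TPM + 1) over the tested members (colour and number) of 15 gene lists, down the plot, in 6 comparisons, across it, with an asterisk where camera with its preset correlation gave an adjusted p under 0.05. G2/M genes read 2.65, 3.07, 0.54, 1.28, -1.70 and -0.49 from left to right, and no list kept its asterisk with an estimated correlation.

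Within Phase I, the comparison of divided with undivided cells of the same culture (div12 against div0) asked how divided and undivided cells differed after the same activation. As lists, G1/S, oxidative phosphorylation and unfolded protein response genes stood higher in divided cells, and MHC class II and resting B cell genes lower, each with only a part of its members called. In the G1/S list 12 of 23 members rose (18 adjusted over the list alone), Gins2 from 72.7 ± 4.15 to 142 ± 0.715 TPM (0.96 ± 0.12), Ccne2, a cyclin of S phase entry, by 0.82 ± 0.20, and the helicase subunit Mcm5 by 0.79 ± 0.13. Camera gave G1/S genes adjusted p = 1.59e-13, and adjusted p = 0.398 with an estimated correlation. In the G2/M list only Cdk1 was called over all genes (0.64 ± 0.16), 12 of 18 rose adjusted over the list alone. Camera gave G2/M genes adjusted p = 9.52e-08, and adjusted p = 0.533 with an estimated correlation. Mki67 (0.54 ± 0.21) and Aurkb (0.35 ± 0.24) did not pass the test. In the DNA repair list 4 of 15 members rose (9 adjusted over the list alone), Chek1 by 0.87 ± 0.21. Camera gave DNA repair genes adjusted p = 4.52e-08, and adjusted p = 0.398 with an estimated correlation. In oxidative phosphorylation 9 of 24 members rose (17 adjusted over the list alone), among them the ATP synthase subunit genes Atp5a1 (0.45 ± 0.07) and Atp5b (0.39 ± 0.09). Camera gave oxidative phosphorylation adjusted p = 1.99e-12, and adjusted p = 0.398 with an estimated correlation. In the unfolded protein response list 6 of 13 members rose (7 adjusted over the list alone), with Hsp90b1 (0.66 ± 0.07) and Sdf2l1 (0.66 ± 0.12), chaperones of that compartment. Camera gave unfolded protein response genes adjusted p = 2.04e-04, and adjusted p = 0.398 with an estimated correlation. In glycolysis 4 of 16 members rose and 0 fell (6 and 2 adjusted over the list alone), with Gapdh (0.69 ± 0.11) and Pgk1 (0.65 ± 0.08). The glycolysis list had camera adjusted p = 0.00718, and adjusted p = 0.533 with an estimated correlation, a call lost without div12 replicate 1 (adjusted p = 0.0791). In ribosome biogenesis 2 of 12 members rose (3 adjusted over the list alone), with the nucleolar Npm1 (0.59 ± 0.07). That list had camera adjusted p = 0.00278, and adjusted p = 0.533 with an estimated correlation, a call lost without div12 replicate 1 (adjusted p = 0.157).

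Among the larger rises were Ccl3 (1.74 ± 0.34), a chemokine, the receptor kinase gene Flt3 (1.43 ± 0.23), Cpd (1.33 ± 0.24), Spp1 (1.31 ± 0.31), which encodes osteopontin, Timd2 (1.25 ± 0.22) and the efflux pump Abcb1b (1.14 ± 0.14). The CDK inhibitor locus Cdkn2a rose by 1.19 ± 0.26 from a low level of 3.19 ± 1.57 TPM. Large falls were those of Ccl5 (-2.63 ± 0.37), Apoe (-1.88 ± 0.38), Pde2a (-1.67 ± 0.24), S1pr1 (-1.65 ± 0.29) and Trpm5 (-1.52 ± 0.22). In the MHC class II list 4 of 6 members fell (6 adjusted over the list alone), with Cd74 (-0.62 ± 0.13) and H2-Ab1 (-0.49 ± 0.10). Camera gave MHC class II genes adjusted p = 5.26e-04, and adjusted p = 0.398 with an estimated correlation. In the resting B cell list 7 of 20 members fell (14 adjusted over the list alone), with Fcmr (-1.35 ± 0.14), the IgM Fc receptor, Il4ra (-0.93 ± 0.08) and Ets1 (-0.76 ± 0.11). Camera gave resting B cell genes adjusted p = 1.77e-07, and adjusted p = 0.398 with an estimated correlation. Bmf fell (-1.09 ± 0.15). Ccnd2 (-0.45 ± 0.14), Ccnd3 (-0.01 ± 0.14), Cdkn1b (-0.17 ± 0.10), Myc (-0.36 ± 0.35) and Prdm1 (-0.92 ± 0.38) did not pass the test. Immediate early genes were called lower as a list (2 of 16 fell, 4 adjusted over the list alone, camera adjusted p = 0.0320), with adjusted p = 0.596 by an estimated correlation. That call was lost with a filter at 5 TPM (adjusted p = 0.0514), no trend (adjusted p = 0.0503) and without div0 replicate 1 (adjusted p = 0.0672) or div12 replicate 1 (adjusted p = 0.217). No list of other cell types was called.

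Limma called 388 genes, 163 higher and 225 lower in div12 (331 and 188 with median-ratio scaling, 200 and 182 with quantile normalization), and 601 in a fit without the naive libraries that was added after seeing the data. The count rested on single libraries: it was 0 without div0 replicate 1 (682 at an unadjusted p under 0.05) and 0 without div0 replicate 2 (831 unadjusted), 119 without div12 replicate 1, 4 without div12 replicate 2, 241 and 237 without div12_48_u replicate 1 or 2, and 607 and 604 without naive replicate 1 or 2. No named gene thus kept its call without either div0 library, and only Il4ra kept it without div12 replicate 2. Median-ratio scaling ended the calls of Cd74 (adjusted p = 0.0606) and H2-Ab1 (adjusted p = 0.105), and quantile normalization that of Chek1 (adjusted p = 0.0552). Beside Birc5, the calls of Ccl3, Spp1, Timd2, Apoe, Ccne2, Cdk1, Chek1, Gapdh, Atp5b, Sdf2l1, Cd74, H2-Ab1 and Cdkn2a were each lost with no filter, the compared groups alone, a replicate block, no trend or the most abundant transcript, in at least 1 of these (adjusted p from 0.0502 to 0.0954).

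The same division comparison in Phase II (div12_48_d against div12_48_u) set cells that divided again against cells that did not, both sorted after 48 h in low anti-CD40. Lists of G1/S, G2/M and passenger complex genes were called higher in cells that divided again, and those of MHC class II and resting B cell genes lower. Birc5 was 2.76-fold higher, Mki67 rose by 1.34 ± 0.21 and Aurkb by 1.05 ± 0.24. All 18 G2/M genes rose (18 adjusted over the list alone), among them Ccnb1 (1.49 ± 0.22), Ccnb2 (1.44 ± 0.17) and Cdk1 (1.43 ± 0.16). Camera gave G2/M genes adjusted p = 9.64e-13, and adjusted p = 0.311 with an estimated correlation. In the G1/S list 20 of 23 members rose (20 adjusted over the list alone), with Gins2 (1.39 ± 0.12), Rrm2 (1.33 ± 0.17) and Mcm5 (1.28 ± 0.13). Camera gave G1/S genes adjusted p = 2.81e-14, and adjusted p = 0.311 with an estimated correlation. All 3 passenger genes rose (3 adjusted over the list alone), Incenp by 0.92 ± 0.23. Camera gave the passenger list adjusted p = 0.00500, and adjusted p = 0.311 with an estimated correlation. The call of Aurkb was lost without div12_48_u replicate 2 (adjusted p = 0.0896) and without div12_48_d replicate 1 or 2 (adjusted p = 0.0780 and 0.0619). That of Incenp was lost without the same libraries (adjusted p = 0.126, 0.108 and 0.0811), with the compared groups alone (adjusted p = 0.0525) and with the most abundant transcript (adjusted p = 0.0569). The D cyclin list was not called (camera adjusted p = 0.346). Inhibitors of cyclin-dependent kinases rose in the same cells: Cdkn2a from 4.54 ± 0.522 to 51.2 ± 8.16 TPM (3.23 ± 0.26), Cdkn2b by 1.81 ± 0.25 and Cdkn1a by 1.67 ± 0.38, the last not without div12_48_u replicate 2 (adjusted p = 0.0911) or div12_48_d replicate 1 (adjusted p = 0.112). The quiescence list that holds them was not called (camera adjusted p = 0.616, direction down, with a median of -0.21 and a mean of 0.13), and Cdkn1b (-0.27 ± 0.10) did not pass the test, except without div12_48_d replicate 2 (adjusted p = 0.0315).

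Jchain, which joins the chains of secreted polymeric antibody, had the largest rise of the named genes, from 27.8 ± 4.67 to 421 ± 60.8 TPM (3.88 ± 0.43). In the plasma cell list 3 of 8 members rose (3 adjusted over the list alone), the others being Xbp1 (0.92 ± 0.12; 0.0641 as adjusted p with the most abundant transcript), a transcription factor of secretory cells, and Tnfrsf17, listed at 0 in div12_48_u and at 1.72 ± 1.25 TPM in div12_48_d, a call at an adjusted p of 0.0441 that was lost without any library outside the naive group (adjusted p from 0.0509 to 0.217). The call of Tnfrsf17 was also lost with a pseudocount of 5 (0.41, adjusted p = 0.0923), and with no filter, the compared groups alone, no trend or the most abundant transcript (adjusted p up to 0.0711). Camera gave plasma cell genes adjusted p = 0.0255, and adjusted p = 0.311 with an estimated correlation, a call lost without div12_48_u replicate 1 (adjusted p = 0.148), without div12_48_d replicate 2 (adjusted p = 0.117), with a filter at 5 TPM (adjusted p = 0.0657) and on the most abundant transcript of each gene (adjusted p = 0.0903, added after seeing the data). Prdm1 (0.46 ± 0.38) did not pass the test. In the list of marginal zone and B1 cell markers 5 of 8 members rose and 2 fell (5 and 2 adjusted over the list alone), including Cd9 (1.83 ± 0.14), Zbtb32 (2.31 ± 0.25) and Bhlhe41 (1.34 ± 0.17). Camera gave marginal zone and B1 markers adjusted p = 0.0227, and adjusted p = 0.311 with an estimated correlation, a call lost in a fit of these groups alone (adjusted p = 0.0575). In the unfolded protein response list 8 of 13 members rose (8 adjusted over the list alone), Sdf2l1 by 1.15 ± 0.12 and Hsp90b1 by 1.14 ± 0.07. Camera gave unfolded protein response genes adjusted p = 9.62e-05, and adjusted p = 0.311 with an estimated correlation. In oxidative phosphorylation 15 of 24 members rose (19 adjusted over the list alone), with Atp5a1 (0.60 ± 0.07). Camera gave oxidative phosphorylation adjusted p = 2.41e-08, and adjusted p = 0.311 with an estimated correlation. In glycolysis 7 of 16 members rose and 1 fell (7 and 1 adjusted over the list alone), with Gapdh among the rises (0.91 ± 0.11). The glycolysis list had camera adjusted p = 0.00362, and adjusted p = 0.427 with an estimated correlation. Further large rises were Spp1 (3.13 ± 0.31), the metalloprotease Adamts7 (2.83 ± 0.29), Ccr10 (2.69 ± 0.28), a homing receptor, and the chemokine Ccl4 (2.59 ± 0.50), the last not without div12_48_d replicate 1 (adjusted p = 0.0557).

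All 6 MHC class II genes fell (6 adjusted over the list alone), H2-Ab1 from 10868 ± 139 to 6724 ± 334 TPM (-0.69 ± 0.10), together with the transactivator Ciita (-1.03 ± 0.10). Camera gave MHC class II genes adjusted p = 1.11e-04, and adjusted p = 0.311 with an estimated correlation. In the resting B cell list 12 of 20 members fell (14 adjusted over the list alone), with Satb1 (-1.66 ± 0.25), Bach2 (-1.18 ± 0.15), a repressor of plasma cell differentiation, and Fcer2a (-0.93 ± 0.13). Camera gave resting B cell genes adjusted p = 1.49e-05, and adjusted p = 0.311 with an estimated correlation. Ifi205 (-3.41 ± 0.52), S1pr3 (-1.95 ± 0.22), Icosl (-1.65 ± 0.19), Gcnt1 (-1.60 ± 0.16) and Pag1 (-1.53 ± 0.18) were the other large falls. Anti-apoptotic Bcl2l1 rose (0.66 ± 0.20, adjusted p = 0.0469, lost without any one of 7 libraries, with adjusted p up to 0.240, and with a replicate block, no filter, the compared groups alone or no trend, with adjusted p from 0.0574 to 0.0950) and Bcl2 fell (-0.58 ± 0.13), as did pro-apoptotic Bmf (-0.82 ± 0.15). The call of Bcl2 was lost without div12_48_u replicate 1 (adjusted p = 0.0919), without div12_48_d replicate 1 (adjusted p = 0.115) and with the compared groups alone (adjusted p = 0.0524), and that of Bmf without div12_48_d replicate 1 (adjusted p = 0.0607). Myc (-0.05 ± 0.35), Ccnd2 (0.07 ± 0.14) and Ccnd3 (0.05 ± 0.14, and 0.35 with the most abundant transcript) did not pass the test. No list of T, NK, myeloid, dendritic, erythroid or platelet markers was called.

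In total 1134 genes were called, 540 higher and 594 lower in div12_48_d, and 669 and 492 with median-ratio scaling. The count was 347 without div12_48_d replicate 1, 553 without div12_48_u replicate 1 and 629 without div12_48_u replicate 2, and 670 in a fit of these groups alone.

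The division contrasts share no library but share each gene's spread, so calls are not independent. Of 163 genes higher in div12 than div0, 141 were also higher in div12_48_d than div12_48_u, against 19.9 expected for independent lists (one-sided Fisher's exact p = 2.86e-111). Of 225 lower genes 171 were also lower in Phase II, against 30.2 expected (one-sided Fisher's exact p = 4.40e-110), and 1 gene, Hbb-b1, was called in opposite directions. Over 4427 genes fold changes had Pearson r = 0.606 and Spearman rho = 0.656, and genes are not independent replicates. The shared count of 312 was 0 without either div0 library, 3 without div12 replicate 2, 95 without div12 replicate 1, 159 and 166 without div12_48_u replicate 1 or 2, and 136 without div12_48_d replicate 1.

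**Figure D3:**
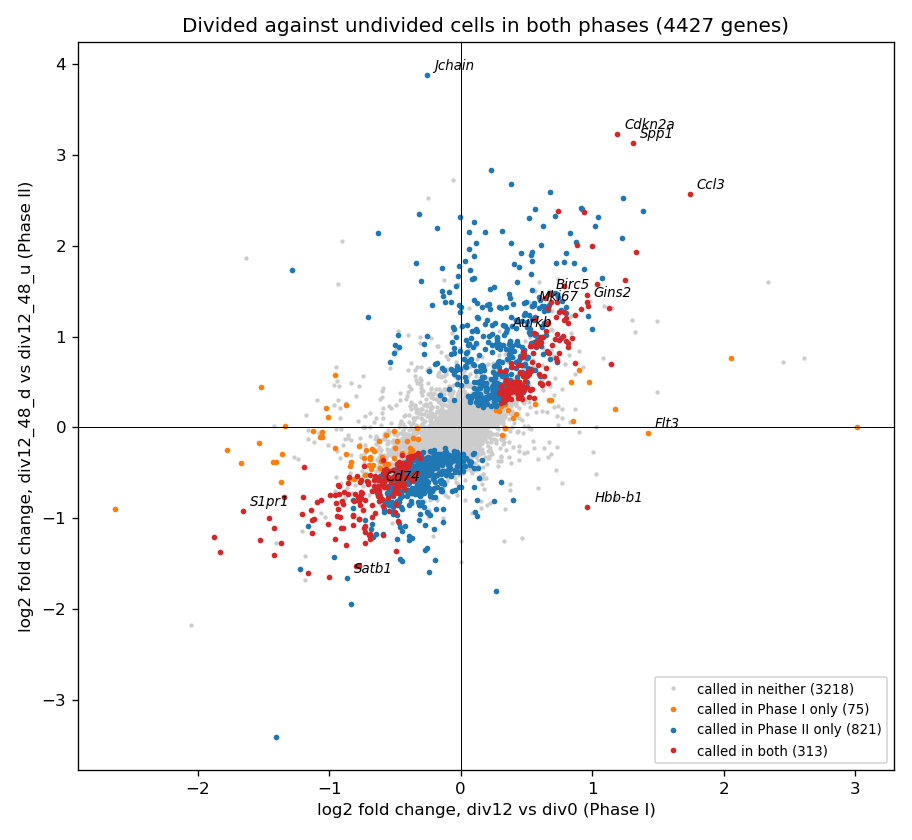
Log2 fold change of each of 4427 genes between divided and undivided cells in Phase I (x axis) and Phase II (y axis), coloured by where limma called them. Genes called in both lie in the upper right and lower left corners, except Hbb-b1, while Jchain stands high in Phase II and near 0 in Phase I.

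Whether these contrasts differed in size was tested directly as the difference of the Phase II and the Phase I contrast. For single genes limma called 0 of 4427 (438 at an unadjusted p under 0.05), and the smallest adjusted p was 0.0539. Cd9, with 1.80 ± 0.20, was among the genes at that value, and Jchain had a difference of 4.13 ± 0.61 (adjusted p = 0.0553). For Birc5 the difference was 0.79 ± 0.21 (adjusted p = 0.217), for Mki67 0.80 ± 0.30 (adjusted p = 0.382) and for Aurkb 0.70 ± 0.33 (adjusted p = 0.553). Those of Myc (0.31 ± 0.49), Ccnd2 (0.52 ± 0.19), Ccnd3 (0.05 ± 0.19), Cdkn1b (-0.10 ± 0.14) and Prdm1 (1.38 ± 0.54) did not pass the test either. As lists, G2/M and G1/S genes had larger contrasts in Phase II, with 0 members of either called (0 adjusted over the list alone). The median difference was 0.73 for G2/M genes (camera adjusted p = 1.05e-09, and adjusted p = 0.658 with an estimated correlation). It was 0.38 for G1/S genes (camera adjusted p = 2.31e-07, and adjusted p = 0.658 with an estimated correlation). Some settings called genes, 15 with a pseudocount of 5, 23 with median-ratio scaling, 8 with quantile normalization, 7 with a filter at 5 TPM, and 11 without the naive libraries. Leaving out single libraries gave between 0 and 11.

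Cells that did not divide again were set against the divided Phase I cells from which they came (div12_48_u against div12), a comparison in which phase, culture time and the number of cells taken for RNA differ together. Cell-cycle lists were called lower, and those of quiescence, resting B cell, MHC class II and immediate early genes higher. Birc5 had the largest fall among the named genes (-2.29 ± 0.15, 4.90-fold), and Aurkb (-1.43 ± 0.24) and Mki67 (-1.68 ± 0.21) fell too. All 18 G2/M genes fell (18 adjusted over the list alone), with Bub1 (-1.96 ± 0.21) and Ccnb2 (-1.94 ± 0.17). Camera gave G2/M genes adjusted p = 1.64e-15, and adjusted p = 0.390 with an estimated correlation. In the G1/S list 20 of 23 members fell (20 adjusted over the list alone), with Gins2 (4.01-fold lower), Uhrf1 (-1.95 ± 0.19), Gmnn (-1.87 ± 0.10) and Rrm2 (-1.82 ± 0.17). Camera gave G1/S genes adjusted p = 4.95e-18, and adjusted p = 0.390 with an estimated correlation. Ccnd3 fell (-0.82 ± 0.14) while Ccnd2 (0.22 ± 0.14) and Myc (0.37 ± 0.35) did not pass the test. Cdkn1b rose by 0.55 ± 0.10. In glycolysis 2 of 16 members rose and 6 fell (2 and 6 adjusted over the list alone), with Gapdh among the falls (-1.18 ± 0.11). The glycolysis list had camera adjusted p = 0.0138, and adjusted p = 0.421 with an estimated correlation. In oxidative phosphorylation 18 of 24 members fell (19 adjusted over the list alone). Camera gave oxidative phosphorylation adjusted p = 7.85e-12, and adjusted p = 0.390 with an estimated correlation. In the unfolded protein response list 2 of 13 members rose and 7 fell (2 and 7 adjusted over the list alone), with Sdf2l1 among the falls (-1.52 ± 0.12). Camera gave unfolded protein response genes adjusted p = 3.95e-04, and adjusted p = 0.390 with an estimated correlation.

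In the quiescence list 11 of 18 members rose and 1 fell (11 and 1 adjusted over the list alone), with Pik3ip1 (2.38 ± 0.24), a brake on PI3 kinase, Klf2 (1.65 ± 0.24), Tob1 (1.03 ± 0.13) and Foxo1 (1.01 ± 0.16). That list had camera adjusted p = 0.0253, and adjusted p = 0.421 with an estimated correlation, and its call was lost without div12_48_u replicate 2 (adjusted p = 0.0570). In the autophagy and lysosome list 15 of 25 members rose (15 adjusted over the list alone), including Mcoln1 (1.02 ± 0.10), a lysosomal channel, and Ulk1 (1.00 ± 0.15), the kinase that starts autophagy. Camera gave autophagy and lysosome genes adjusted p = 0.00384, and adjusted p = 0.403 with an estimated correlation. In the immediate early list 9 of 16 members rose (10 adjusted over the list alone), with Egr1 (3.42 ± 0.54), Fos (3.29 ± 0.72; adjusted p = 0.0542 without div12_48_u replicate 2), Egr2 (2.93 ± 0.42) and Egr3 (2.20 ± 0.38). Camera gave immediate early genes adjusted p = 0.00167, and adjusted p = 0.421 with an estimated correlation. Whether signalling, sorting or handling raised them was not tested. In the resting B cell list 12 of 20 members rose and 1 fell (12 and 1 adjusted over the list alone), with S1pr1 (3.50 ± 0.29), Fcmr (2.46 ± 0.14) and Satb1 (2.20 ± 0.25). Camera gave resting B cell genes adjusted p = 9.76e-04, and adjusted p = 0.403 with an estimated correlation. In the MHC class II list 5 of 6 members rose (5 adjusted over the list alone), Ciita by 0.72 ± 0.10 and Cd74 by 0.69 ± 0.13 (adjusted p = 0.0527 with the compared groups alone). Camera gave MHC class II genes adjusted p = 0.0316, and adjusted p = 0.421 with an estimated correlation, a call lost with median-ratio scaling (adjusted p = 0.103), with the compared groups alone (adjusted p = 0.0755), without div12 replicate 1 (adjusted p = 0.0571) and without div12_48_u replicate 2 (adjusted p = 0.0513).

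In the BCL2 family 5 of 13 members rose and 4 fell (6 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 1.00). Members for and against apoptosis moved both ways. Of those that promote it, Bmf rose by 1.68 ± 0.15, Bbc3, which encodes PUMA, by 1.61 ± 0.19, Bcl2l11, which encodes BIM, by 1.24 ± 0.33 and Bax by 0.26 ± 0.07, while Bid (-0.78 ± 0.19) and Bak1 (-0.32 ± 0.11) fell. Of those that act against it, Bcl2 rose (0.68 ± 0.13), while Bcl2l1 (-0.80 ± 0.20) and Bcl2a1a (-0.68 ± 0.19) fell. The call of Bcl2l11 was lost without div12 replicate 2 (adjusted p = 0.0983) and without div12_48_u replicate 1 or 2 (adjusted p = 0.0741 and 0.0706). That of Bcl2l1 was lost without div12 replicate 1 (adjusted p = 0.0850), without div12_48_u replicate 2 (adjusted p = 0.0887) and with the compared groups alone (adjusted p = 0.0563). Bid lost its call without div12 replicate 2 (adjusted p = 0.0604) or div12_48_u replicate 2 (adjusted p = 0.0695). Without any one library of these groups the calls of Bax (adjusted p from 0.0532 to 0.0803), Bcl2a1a (adjusted p from 0.0586 to 0.104) and Bak1 (adjusted p from 0.0796 to 0.194) were lost. Bax lost its call also with median-ratio scaling (adjusted p = 0.606) and quantile normalization (adjusted p = 0.0557), and Bak1 in 10 further settings (adjusted p from 0.0503 to 0.0750).

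Apoe had the largest rise of the named genes, from 27.1 ± 2.27 to 931 ± 337 TPM (5.00 ± 0.38), and Tgfb3 (4.01 ± 0.79) and Actn1 (3.20 ± 0.46) rose as well. Lists of T, NK, myeloid, dendritic, erythroid and platelet markers were not called (camera adjusted p = 0.938, 0.934, 0.445, 0.400, 0.894 and 0.806). Single markers moved, with Adgre1 of the myeloid list (1.54 ± 0.41) and Lck of the T cell list (1.37 ± 0.09) rising and Flt3 of the dendritic list falling (-1.48 ± 0.23). The call of Adgre1 was lost without div12 replicate 1 (adjusted p = 0.101), without div12_48_u replicate 1 or 2 (adjusted p = 0.0850 and 0.0683) and with the most abundant transcript (adjusted p = 0.0533). In the platelet list 2 of 3 members rose and 1 fell (2 and 1 adjusted over the list alone). Prdm1 rose by 1.72 ± 0.38 to 8.32 ± 0.0833 TPM. Further falls were Fscn1 (-2.23 ± 0.37), an actin bundler, Csrp2 (-2.20 ± 0.14), Gbp2b (-2.08 ± 0.24) and Tmem176b (-2.03 ± 0.51), the last not without div12 replicate 2 (adjusted p = 0.0790) or div12_48_u replicate 2 (adjusted p = 0.0850). Limma called 1828 genes, 1225 higher and 603 lower in div12_48_u, with a median over all genes of 0.16. With median-ratio scaling 816 were higher and 952 lower, with quantile normalization 851 and 856, and the count was 1213 without div12_48_u replicate 1 and 1216 without div12 replicate 2.

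Cells that divided again were compared with the same Phase I cells (div12_48_d against div12), with the same differences of phase. Their G2/M genes lay nearer to div12 than those of div12_48_u did, with a median of -0.49 against -1.70. Birc5 was still lower (-0.83 ± 0.15; without div12_48_d replicate 2 its adjusted p was 0.0739), whereas Aurkb (-0.38 ± 0.24) and Mki67 (-0.34 ± 0.21) did not pass the test. In the G1/S list 9 of 23 members fell (13 adjusted over the list alone), with Uhrf1 (-0.74 ± 0.19), Gmnn (-0.66 ± 0.10) and Gins2 (-0.62 ± 0.12). The call of Uhrf1 was lost in 8 settings, among them without div12 replicate 1 (adjusted p = 0.161) and without either div12_48_d library (adjusted p of at least 0.0903). That of Gins2 was lost without div12 replicate 2 (adjusted p = 0.0631), without div12_48_d replicate 2 (adjusted p = 0.0873) and with the compared groups alone (adjusted p = 0.0558). Camera gave G1/S genes adjusted p = 1.74e-09, and adjusted p = 0.408 with an estimated correlation. No G2/M gene was called over all genes, 9 of 18 fell adjusted over the list alone, Ccna2 had -0.53 ± 0.17 (adjusted p = 0.0263 with median-ratio scaling). Camera gave G2/M genes adjusted p = 3.85e-07, and adjusted p = 0.427 with an estimated correlation. Ccnd3 fell (-0.78 ± 0.14; adjusted p = 0.0673 without div12_48_d replicate 2), and Ccnd2 (0.30 ± 0.14), Cdkn1b (0.28 ± 0.10) and Myc (0.32 ± 0.35) did not pass the test, except Cdkn1b without div12_48_d replicate 1 (adjusted p = 0.0414). Jchain rose from 13.8 ± 8.07 to 421 ± 60.8 TPM (4.94 ± 0.43), Xbp1 by 0.65 ± 0.12 and Prdm1 from 1.82 ± 0.179 to 12.3 ± 5.12 TPM (2.18 ± 0.38), in a plasma cell list where 4 of 8 members rose (6 adjusted over the list alone). The call of Xbp1 was lost on the most abundant transcript (adjusted p = 0.395), with the compared groups alone (adjusted p = 0.0597), without div12 replicate 2 (adjusted p = 0.0667) and without div12_48_d replicate 2 (adjusted p = 0.0726). That of Prdm1 was lost without div12 replicate 2 (adjusted p = 0.0526) and without div12_48_d replicate 2 (adjusted p = 0.0643). Camera gave plasma cell genes adjusted p = 0.00260, and adjusted p = 0.408 with an estimated correlation. In the marginal zone and B1 list 6 of 8 members rose and 1 fell (6 and 1 adjusted over the list alone), with Bhlhe41 (2.36 ± 0.17), Cd9 (2.16 ± 0.14) and Cd5 (1.63 ± 0.11). Camera gave marginal zone and B1 markers adjusted p = 0.00198, and adjusted p = 0.408 with an estimated correlation.

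In the immediate early list 7 of 16 members rose (8 adjusted over the list alone), with Egr2 (2.86 ± 0.42) and Egr1 (2.15 ± 0.54), the latter a call lost in 8 settings, among them without div12 replicate 1 (adjusted p = 0.147) and without div12_48_d replicate 1 or 2 (adjusted p = 0.0892 and 0.174). Camera gave immediate early genes adjusted p = 2.52e-04, and adjusted p = 0.408 with an estimated correlation. Nfatc1 rose by 2.11 ± 0.20. In the quiescence list 7 of 18 members rose (11 adjusted over the list alone), with Cdkn2a (2.49 ± 0.26), Klf2 (1.93 ± 0.24) and Pik3ip1 (1.72 ± 0.24). Camera gave quiescence genes adjusted p = 6.59e-04, and adjusted p = 0.408 with an estimated correlation. In the interferon-induced list 10 of 21 members fell (14 adjusted over the list alone), including Rtp4 (-2.12 ± 0.37; adjusted p = 0.0505 with the compared groups alone), Ifit2 (-1.29 ± 0.17) and Mx1 (-1.01 ± 0.27). The call of Mx1 was lost in 8 settings, among them without div12 replicate 1 or 2 (adjusted p = 0.111 and 0.144) and without div12_48_d replicate 1 or 2 (adjusted p = 0.162 and 0.0565). Camera gave interferon-induced genes adjusted p = 1.74e-09, and adjusted p = 0.408 with an estimated correlation. Bbc3 rose by 1.19 ± 0.19. The largest rises beside Jchain were Pstpip2 (4.05 ± 0.34), Apoe (3.80 ± 0.38), Adamts7 (3.50 ± 0.29), Actn1 (3.50 ± 0.46) and Spp1 (3.41 ± 0.31), and further large falls Fscn1 (-2.21 ± 0.37), Ffar2 (-2.03 ± 0.31), Slamf1 (-1.75 ± 0.13), Cd1d2 (-1.74 ± 0.36), Carmil3 (-1.71 ± 0.29) and Ache (-1.69 ± 0.41). Of these falls, that of Ache was lost in 7 settings (adjusted p from 0.0524 to 0.183), that of Cd1d2 in 4 (adjusted p from 0.0585 to 0.103), that of Carmil3 without div12_48_d replicate 2 (adjusted p = 0.0617) and that of Fscn1 with the compared groups alone (adjusted p = 0.0593). Lck, a kinase also known from T cells, rose from 144 ± 10.3 to 433 ± 16.3 TPM (1.59 ± 0.09), in a T cell marker list that was not called (camera adjusted p = 0.340), and Adgre1, a macrophage marker, to 171 ± 46.5 TPM (2.21 ± 0.41; adjusted p = 0.0595 without div12 replicate 1 and 0.0857 without div12_48_d replicate 2), in a myeloid list that was not called (camera adjusted p = 0.449). Limma called 706 genes, 525 higher and 181 lower in div12_48_d (442 and 428 with median-ratio scaling, 382 and 364 with quantile normalization). The count was 227 without div12_48_d replicate 2, 301 and 446 without div12 replicate 2 or 1, and 412 in a fit of these groups alone.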

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

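Tests of other-cell RNA in the naive libraries, of unequal other-cell RNA between them, of a general widening in Phase II and of undivided cells in both phases were chosen only after the result was seen.

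As lists, 7 groups of genes had division contrasts that differed between the phases by camera with its preset correlation, while limma called 0 single genes for the difference (438 at an unadjusted p under 0.05) and 0 lists passed with an estimated correlation. The median log2 difference, Phase II minus Phase I, was 0.73 over 18 G2/M genes (adjusted p = 1.05e-09) and 0.38 over 23 G1/S genes (adjusted p = 2.31e-07). It was 0.70 over 3 passenger complex genes (adjusted p = 0.0166), 0.81 over 8 plasma cell genes (adjusted p = 0.00791) and 0.56 over 8 marginal zone and B1 markers (adjusted p = 0.00874). It was 0.20 over 13 unfolded protein response genes (adjusted p = 0.0298) and -0.20 over 6 MHC class II genes (adjusted p = 0.0106). With an estimated correlation the adjusted p was 0.735 for the unfolded protein response and 0.658 for the others. Single libraries or settings ended some calls: the unfolded protein response without either naive library, div12 replicate 2, div12_48_u replicate 2 or div12_48_d replicate 1 (adjusted p from 0.0814 to 0.146) and with median-ratio scaling (adjusted p = 0.0519), the passenger list without either naive library, div12_48_u replicate 2 or div12_48_d replicate 1 (adjusted p from 0.0504 to 0.0672), plasma without div12_48_u replicate 1 (adjusted p = 0.0846), and marginal zone and B1 without div12 replicate 1 (adjusted p = 0.0584). The compared groups alone ended the calls of the passenger list (adjusted p = 0.0564) and the unfolded protein response (adjusted p = 0.0875), which no trend ended too (adjusted p = 0.0715), and the most abundant transcript, added after seeing the data, ended those of the unfolded protein response (adjusted p = 0.0910) and plasma cell genes (adjusted p = 0.0765).

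For the larger Phase II difference of cell-cycle genes, the choice among scalings was excluded as the cause. The median over 41 genes was 0.51 on TPM, 0.48 with median-ratio scaling and 0.55 with quantile normalization, with 39 of 41 genes above 0. A general widening of differences in Phase II could not be decided: the SD of fold changes outside the cell-cycle lists, corrected for error, was 1.60 times that of Phase I, and the cell-cycle medians of 0.54 and 1.15 had a ratio of 2.13. By arithmetic the difference is the change of divided cells between the phases minus that of undivided cells, with medians of -0.42 (div12_48_d against div12) and -1.04 (div12_48_u against div0, 35 of 41 lower; -1.13 with median-ratio scaling and -1.14 with quantile normalization). Both medians were below 0 and that of undivided cells was further from 0, which restates the difference, is no independent evidence and leaves its cause open. Phase remains confounded with culture time, sorting and cell input, none of which was tested.

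Marker genes of other spleen cells stood lower after activation than in naive libraries. Of 26 markers of 6 cell types with at least 10 TPM in naive cells, 80.8% (21) were lower in both div0 and div12, against 37.9% of 3318 genes at that level. RNA from other cells in the naive libraries may account for this, with Hba-a1 (2116 ± 217 TPM), C1qa (158 ± 129.7) and Klra8 (40.3 ± 15.8) among those markers and no purification stated for these cells in what was used here. Choice of scaling was excluded as the cause (median -3.65 with median-ratio, -3.82 on TPM, -3.42 with quantile), but no scaling measures RNA per cell. Loss of these transcripts from B cells themselves stays open and was not tested.

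Immediate early genes were higher in naive libraries than in div12, and 13 of 16 were higher in naive replicate 1 than 2, with a median log2 ratio of 1.24. The same ratio was -1.42 for myeloid, -1.73 for erythroid, -0.37 for NK, -0.20 for T cell and 0.05 for platelet markers. These medians argue against unequal RNA from those cells as the cause of that difference between naive libraries. Unequal RNA from other cells was not tested and stays open. Plasma cell genes summed to 2391 and 1361 TPM in naive replicates 1 and 2, but Jchain had 147 and 331. Choice of scaling was excluded for the difference from div12 (median -2.94 with median-ratio, -3.21 on TPM, -2.80 with quantile), but no scaling measures RNA per cell. Induction in handling and a state of resting cells stay open and were not tested.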

How the results depend on the processing

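The fit without the naive group and the most abundant transcript were tests chosen only after the result was seen. Of 261 named gene results 233 were called, 0 of these reversed under any alternative, 63 lost their call without some library and 36 in another setting apart from a fold of at least 2. No list call changed direction. Unless stated, the cause of a change was not tested. A fold of at least 2 left fewer genes by construction: 856 and 1220 for div0 and div12 against naive, 49 for div12 against div0, 249 for div12_48_d against div12_48_u, 399 and 244 for div12_48_u and div12_48_d against div12, and 19 shared by the division contrasts. With an estimated correlation 0 lists were called in all 7 comparisons. Fry called 32 lists for div12 against naive, 6 for div12 against div0 and 0 for the difference.

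For div12 against div0, 162 genes were called with no filter, 236 with the compared groups alone (fewer libraries), 247 with the replicate block, 183 without trend, 601 without the naive group and 223 with the most abundant transcript. Fits of the compared groups alone gave 670 genes for div12_48_d against div12_48_u and 412 for div12_48_d against div12. For the difference of contrasts the counts were 15 with a pseudocount of 5, 7 with a filter at 5 TPM, 23 with median-ratio scaling, 8 with quantile normalization, 11 with the compared groups alone, 3 with the block, 11 without the naive group and 2 with the most abundant transcript. The shared count was 137 with no filter, 112 with the compared groups alone, 144 without trend and 177 with the most abundant transcript. Replicate numbers were no guide to pairs, as 3 of 10 correlations of replicate differences between groups were above 0.1 (-0.24 to 0.20).

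Leaving out single libraries gave 1573 to 2382 genes and 20 to 23 lists for div0 against naive, 2497 to 2928 and 18 to 23 for div12 against naive, 0 to 607 and 10 to 14 for div12 against div0, 347 to 1432 and 13 to 16 for div12_48_d against div12_48_u, 1213 to 2169 and 16 to 20 for div12_48_u against div12, 227 to 962 and 14 to 17 for div12_48_d against div12, 0 to 11 and 5 to 10 for the difference, and 0 to 464 shared genes.

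Values near 0 that did not pass the test changed sign. For div12 against div0, Ccnd3 was -0.01, and 0.10 with median-ratio scaling, 0.0164 with quantile normalization, 0.0467 with the most abundant transcript and -0.11 to 0.10 without single libraries. For div12_48_d against div12_48_u, Myc was -0.05, and 0.0219 and 0.0016 with those scalings and -0.20 to 0.10 without single libraries, Ccnd2 ran from -0.0676 to 0.22 and Ccnd3 from -0.0226 to 0.11, with 0.35 for its most abundant transcript. For the difference, Ccnd3 ran from -0.0537 to 0.15, with 0.30 for its most abundant transcript, and Cdkn1b from -0.23 to 0.0243. Depth, unknown here, limits what can be said of genes near 0 TPM.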

Other observations

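The correlation for a partial return to the resting state was planned before its result was seen, and the counts of genes by direction beside it were not.

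Ribosome biogenesis, histone and inhibitor of apoptosis lists follow for some comparisons. In div12_48_d against div12_48_u, 4 of 12 members rose (6 adjusted over the list alone) in ribosome biogenesis, with camera adjusted p = 7.24e-04, and adjusted p = 0.441 with an estimated correlation. Among replication-dependent histone genes 3 of 31 members rose (1 adjusted over the list alone), with camera adjusted p = 0.00586, and adjusted p = 0.311 with an estimated correlation, a call lost without div12_48_u replicate 1 (adjusted p = 0.148). In div12_48_u against div12, 6 of 12 members fell (6 adjusted over the list alone) in ribosome biogenesis, with camera adjusted p = 9.76e-04, and adjusted p = 0.421 with an estimated correlation. Of histone genes 1 of 31 members rose and 7 fell (1 and 7 adjusted over the list alone), with camera adjusted p = 8.58e-04, and adjusted p = 0.390 with an estimated correlation. Among inhibitor of apoptosis genes 1 of 3 members fell (2 adjusted over the list alone) in div12_48_d against div12, with camera adjusted p = 0.0350, and adjusted p = 0.408 with an estimated correlation, a call lost with quantile normalization (adjusted p = 0.0704), with the most abundant transcript (adjusted p = 0.152) and without div12 replicate 2 (adjusted p = 0.0743).

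Further lists were called in comparisons where they are not yet given. In div12_48_u against div12, 7 of 21 members fell (6 adjusted over the list alone) in the interferon-induced list, with camera adjusted p = 3.54e-04, and adjusted p = 0.421 with an estimated correlation. In DNA repair 14 of 15 members fell (15 adjusted over the list alone), with camera adjusted p = 1.65e-10, and adjusted p = 0.390 with an estimated correlation. In cholesterol synthesis 9 of 13 members fell (10 adjusted over the list alone), with camera adjusted p = 3.77e-05, and adjusted p = 0.421 with an estimated correlation. In the autophagy and lysosome list 7 of 25 members rose (13 adjusted over the list alone) in div12_48_d against div12, with camera adjusted p = 0.00362, and adjusted p = 0.408 with an estimated correlation.

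Further called lists follow, with members called when adjusted over the list alone in square brackets and the camera adjusted p. For div12 against naive, lists called higher were passenger (3 of 3 rose [3], adjusted p = 0.00130), DNA repair (15 of 15 rose [15], adjusted p = 3.44e-10), ribosomal protein (16 of 16 rose [16], adjusted p = 1.30e-09), one-carbon (3 of 4 rose [3], adjusted p = 0.00552) and cholesterol synthesis (10 of 13 rose [10], adjusted p = 9.31e-06). So were the BCL2 family (5 of 13 rose and 2 fell [5 and 2], adjusted p = 0.0222) and D cyclins (6 of 10 rose and 3 fell [6 and 3], adjusted p = 0.0348), both lost with a filter at 5 TPM (adjusted p = 0.0595 and 0.0597) or quantile normalization (adjusted p = 0.0897 and 0.0876) and the latter with median-ratio scaling (adjusted p = 0.0564). For div12 against div0 they were ribosomal protein (4 of 16 rose [5], adjusted p = 2.43e-04), one-carbon (2 of 4 rose [3], adjusted p = 0.00949) and cholesterol synthesis (1 of 13 rose [1], adjusted p = 0.00395), lost without div12 replicate 2 (adjusted p = 0.0526), with the compared groups alone (adjusted p = 0.0513) and without div12 replicate 1 (adjusted p = 0.157) in that order. For div12_48_d against div12_48_u they were DNA repair (10 of 15 rose [10], adjusted p = 9.00e-08), ribosomal protein (3 of 16 rose [3], adjusted p = 0.00362), one-carbon (2 of 4 rose [2], adjusted p = 0.0243) and cholesterol synthesis (3 of 13 rose [3], adjusted p = 0.0172). Of these, ribosomal protein was lost without div12_48_u replicate 1 (adjusted p = 0.178), and one-carbon and cholesterol without div12_48_u replicate 2 (adjusted p = 0.0522 and 0.189) or div12_48_d replicate 1 (adjusted p = 0.0864 and 0.115). Called lower in div12_48_u against div12 were passenger (3 of 3 fell [3], adjusted p = 0.00125), ribosomal protein (6 of 16 fell [6], adjusted p = 3.95e-04), one-carbon (3 of 4 fell [3], adjusted p = 0.00408) and D cyclins (2 of 10 rose and 5 fell [2 and 5], adjusted p = 0.0445), ribosomal protein not with quantile normalization (adjusted p = 0.0877) and D cyclins not in 8 settings (adjusted p from 0.0517 to 0.0750). Called lower in div12_48_d against div12 were DNA repair (0 of 15 fell [0], adjusted p = 9.44e-05), oxidative phosphorylation (1 of 24 fell [0], adjusted p = 6.32e-05), cholesterol synthesis (1 of 13 fell [1], adjusted p = 8.79e-04), MHC class II (1 of 6 fell [1], adjusted p = 0.0134) and passenger (1 of 3 fell [1], adjusted p = 0.0350), MHC class II not with quantile normalization (adjusted p = 0.110) and passenger not in 6 settings (adjusted p from 0.0517 to 0.142). With an estimated correlation the adjusted p of these lists was at least 0.278, 0.506, 0.311, 0.390 and 0.408 in the order given.

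Summed TPM of the T cell markers was 158 in div12, 386 in div12_48_u and 455 in div12_48_d on average, of which Lck alone made up 144 ± 10.3, 374 ± 38.8 and 433 ± 16.3, a list called in neither Phase II comparison with div12 (camera adjusted p = 0.938 and 0.340).

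Cells that did not divide again may have moved part of the way back toward the resting state. Across 4277 genes outside the cell-cycle, immediate early and other-cell lists, the undivided minus divided change of Phase II and the naive minus div0 change, which share no library, had Pearson r = 0.158 and Spearman rho = 0.310, and genes are not independent replicates. The r was 0.163 with median-ratio scaling, 0.202 with quantile normalization and 0.0791 to 0.221 without single libraries. The bounds set in advance were above 0.2 for a return and under 0.1 against it, so the test did not decide. Of 591 genes higher in div12_48_u than div12_48_d, 383 were lower in div0 than naive, against 234 expected for independent lists, which these are not, and 33 were higher. Of 484 genes higher in div12_48_d, 226 were higher in div0 than naive, against 70.2 expected, and 87 were lower.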
